A study of Lithobates pipiens with 72 samples.

How the data were processed

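Gene expression was measured by RNA sequencing of whole leopard frog tadpoles exposed for 96 h to TNT, NQ, MeNQ or IMX-101, with 72 libraries in 18 groups of 4, each a pool of 5 tadpoles from 1 beaker. Per the labels' protocols, only RNA that met set limits of integrity and purity was pooled, and libraries were made with a stranded kit for poly-A mRNA. The sample labels and the series text give different targets for 3 of the doses, and doses and groups were taken from the labels. No library was left out.

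Per the submitters' processing notes, the authors split the reads by sample with bcl2fastq 1.8.4. They made the deposited values, estimated counts per transcript, with Salmon, whose version is not given in the sources used here. One deposited table holds 1 column per sequencing run (134 columns), and 4 others hold 1 value per library. On the values, the latter equal the mean of a library's runs to within 5.5e-05. In the header of the first table, the sample numbers in the run names of NQ 3750 mg/L A and C are exchanged for 1 run each, while the dose and letter given there match the column titles. The titles were used, and which of these 2 libraries those runs belong to rests on them. The runs of each library were summed here, for 62 libraries with 2 runs and 10 with 1 run. The correlation of the 2 runs of a library ran from 0.784 to 0.922, and in 47 libraries the first run was closer to its own second run than to any other run. The deposited E-value column gives the strength of each transcript's match to a Xenopus protein, per the file headers, and 47 rows had an E-value over 1e-05. The reference transcriptome, the search tool and any filter behind the tables are not given in the sources used here. Of 19128 transcripts, 11334 carried a protein name (9533 distinct names) and 7794, with 44.4% of the counts, carried none. Raw reads were not analysed here, nor were skin bacteria or the water chemistry.

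Library totals had a median of 10.8 M counts. Counting intervals and floors cover counting error only. Counts were rounded and analysed with edgeR 4.0.16 in R 4.3.3. Each exposure was 1 model with all of its libraries. Rows were kept by filterByExpr with default settings, libraries were scaled by TMM, and groups were compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. A dose trend was 1 slope per dose step. The MeNQ and NQ responses were compared as a contrast of contrasts in 1 model of their 40 libraries, with a 95% interval. Standard errors of log2 fold changes were taken as the size of the change over the square root of F. Levels in CPM (counts scaled to the library total) used TMM-scaled totals. A fold against a group with no counts was computed against a floor of 3 counts over the group and is a lower bound, and with 1 to 3 counts a ratio with its exact binomial interval is given.

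Gene lists, 46 in all with 1472 gene symbols, were fixed beforehand, and 764 symbols matched a protein name by written name patterns, because none of the hit accessions was in the reference table of symbols. A list was tested with 5 or more measured genes, by camera (limma 3.58.1) with a preset correlation of 0.01, and again with the correlation estimated from the data and with fry. Where a name had several transcripts, the one with the highest mean count stood for the gene. Named genes followed a rule: at the highest dose of each exposure, among named transcripts that passed, with a mean of at least 1 CPM and all 4 exposed libraries on the same side of all 4 controls, the 8 largest rises and 8 largest falls. Up to 4 members per list with the smallest adjusted p were added, called or not. For MeNQ against NQ the 5 largest differences in each direction at 36 mmol/L were taken, and in a comparison with fewer than 5 calls all of them. Only part of the genes so chosen is named in the text.

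Comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. Those alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, a 2-fold minimum, counts summed by protein name, only the 8 libraries compared, log10 dose, the replicate letter as a block, the estimated correlation, fry, and each library left out in turn. Added later were the mean of the runs, the deepest run of each library, the sequencing lane as a term, leaving out libraries of a single run, and comparisons within the IMX-101 run sets. For the overlaps between exposures, leaving out libraries, the size factors and the summing by name were also added later. Overlaps counted transcripts tested and called in both. The test was checked on simulated negative binomial counts with the mean and spread of each transcript and known changes added to the exposed group. At 3.4 mg/L TNT, 193 of 12059 transcripts were changed. There edgeR recovered 12.1%, 21.0% and 49.2% of changes of 1.5, 2 and 4-fold, and none of its calls was false. At 36 mmol/L the difference between compounds was recovered in 5.97%, 10.4% and 45.5%. In the same simulated data 28.3% to 41.4% of DESeq2 Wald calls were false over the 4 exposures, against 0 to 3.77% for edgeR. Exact permutation tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.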

Results

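Whole-body RNA of leopard frog (Rana pipiens) tadpoles was sequenced after 96 h in clean water or in water holding a munition compound. Tadpoles were aged 7 to 10 d when exposure began. The exposures were TNT (trinitrotoluene, a nitroaromatic explosive), NQ (nitroguanidine), MeNQ (methylnitroguanidine, which carries a methyl group that NQ lacks) and IMX-101, an insensitive-munition mixture whose components include NTO and NQ. Each exposure had its own control group. The 3 TNT doses were 1.5, 2.3 or 3.4 mg/L, and the 3 IMX-101 doses were 10, 20 or 40 mg/L. NQ was given at 30, 150, 750 and 3750 mg/L and MeNQ at 34, 170, 851 and 4225 mg/L, which are matched at 0.3, 1.4, 7.2 and 36 mmol/L. Each of the 18 groups held 4 libraries (A to D), each a pool of 5 tadpoles from 1 beaker. The values were estimated counts per transcript over 19128 transcripts, and each transcript was named by its closest Xenopus protein. Library totals ran from 1.67 (TNT control A) to 21.7 M counts. Medians were 9.23 M for NQ, 10.1 M for TNT, 14 M for MeNQ and 9.51 M for IMX-101. Levels are given in CPM, counts scaled to the library total. Unless stated otherwise, changes are log2 fold changes against the control of the same exposure, ± their standard error with 4 libraries per group, and adjusted p is edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

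The first question was what TNT, the legacy explosive, changed in the tadpoles and at which dose. At 3.4 mg/L the most certain change was in a transcript named apoptosis-inducing factor 2-like, an oxidoreductase, which rose by 3.99 ± 0.13 (adjusted p = 5.37e-10), from 54.1 ± 4.57 (SD) CPM in the control to 864 ± 64.3. A transcript named only cytochrome P450 rose by 6.18 ± 0.60 (adjusted p = 1.15e-05), from 5.56 to 408 CPM. Transcripts of hsp70, a chaperone induced by damaged protein, rose by 4.60 ± 0.47 (adjusted p = 1.84e-05), and those of the cystine/glutamate transporter, which imports cystine for glutathione synthesis, by 3.66 ± 0.24 (adjusted p = 3.49e-07). The transmembrane 4 L6 family member 20 fell by 3.13 ± 0.31 (adjusted p = 1.15e-05) and the pulmonary surfactant-associated protein D-like lectin, a secreted pathogen-binding protein, fell by 3.69 ± 0.44, from 909 to 70.6 CPM (adjusted p = 6.28e-05). Proteinase-activated receptor 1-like changed by -4.20 ± 1.00 (adjusted p = 0.0123). In total, 1516 of 12648 transcripts changed at 3.4 mg/L, 806 upward and 710 downward, of which 448 changed at least 2-fold. The balance turned under other scaling or tests, to 712 up and 788 down with DESeq2 size factors and 1010 and 1066 by the DESeq2 Wald test. In each gene named for its change here, all 4 exposed libraries lay on the same side of all 4 controls.

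Some of the widest changes ended at or near a count of 0, where only a bound or a counting interval can be given. Integrin alpha-5-like had no counts in the 4 TNT controls and 179 counts at 3.4 mg/L, at least 40.4-fold higher against a floor of 3 counts over the group. An adult alpha globin transcript had 2 counts in the controls and 525 at 3.4 mg/L, a depth-scaled ratio of 178 (95% counting interval 48.95 to 1471). A transcript named as a probable hypophosphite dioxygenase had 110 control counts and none at 3.4 mg/L, at least 54.2-fold lower. Fibroblast growth factor 19, the bile-acid-responsive gut hormone, had 3 counts over the 4 libraries at 3.4 mg/L and was 51.7-fold lower than in the control (95% counting interval 17.2 to 255). These bounds and intervals cover counting error only.

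Genes of the NRF2 antioxidant response rose as a group under TNT. Of 18 measured members, 10 rose at 3.4 mg/L and none fell, with the same 10 adjusted over the list alone, and the list's median was 2.01 (camera adjusted p = 4.42e-18). With an estimated correlation between genes the list kept its call (adjusted p = 0.000651). Its members included Fth1, the ferritin heavy chain that stores iron (1.19 ± 0.08, adjusted p = 2.84e-07), aldose reductase-like (0.93 ± 0.08, adjusted p = 2.65e-06) and kelch-like ECH-associated protein 1, the NRF2 inhibitor KEAP1 (2.24 ± 0.23, adjusted p = 1.84e-05). Of the 17 conjugation enzymes, 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.00996), and the call was lost at adjusted p = 0.116 with an estimated correlation. Those that rose included glutathione S-transferase alpha 1 (1.54 ± 0.13), thiopurine S-methyltransferase (2.03 ± 0.19) and UDP-glucuronosyltransferase 1-1-like (1.18 ± 0.12). Among 8 members of cytochrome P450 families 2 and 3, only cytochrome P450 3A29-like (1.84 ± 0.10, adjusted p = 8.88e-08) and CYP2J2 (0.70 ± 0.11) rose, also adjusted over the list alone (list adjusted p = 0.00151; adjusted p = 0.0342 with an estimated correlation). Cytochrome P450 4B1-like, measured in the list of fatty acid oxidation, rose by 1.99 ± 0.12.

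Haemoglobin and proteasome genes also rose. Of 6 measured genes of haemoglobin and haem synthesis, 4 rose, also adjusted over the list alone, with a list median of 2.30 (camera adjusted p = 1.45e-07; adjusted p = 0.00611 with an estimated correlation). Haemoglobin subunit alpha-5 rose by 2.49 ± 0.30, beta-2-like by 2.10 ± 0.36 and alpha-3, the most abundant, by 1.56 ± 0.27, from 3144 to 9243 CPM (adjusted p = 0.00131). Globin transcripts are near-identical copies, so reads may be split among them and the single values are uncertain. Of 9 proteasome subunits, 7 rose, also adjusted over the list alone, among them PSMA1 (0.65 ± 0.04, adjusted p = 3.76e-07), PSMD6 (0.72 ± 0.06) and PSMB5-like (0.95 ± 0.09), for a list median of 0.50 (camera adjusted p = 2.19e-10; adjusted p = 0.0161 with an estimated correlation). In the list of haem degradation and iron handling, 2 of 6 rose, over all genes and adjusted over the list alone: Fth1 and cytoplasmic aconitate hydratase (0.88 ± 0.12), which bind or sense iron and do not degrade haem (camera adjusted p = 0.000144; adjusted p = 0.0161 with an estimated correlation). Of 5 measured genes of cholesterol synthesis 4 rose, also adjusted over the list alone, including diphosphomevalonate decarboxylase-like (1.17 ± 0.19) and squalene monooxygenase-like (1.23 ± 0.23) (camera adjusted p = 0.00138; adjusted p = 0.0185 with an estimated correlation). Isocitrate dehydrogenase of the cytoplasm, which supplies NADPH, rose by 1.09 ± 0.10, methionine adenosyltransferase II alpha by 0.73 ± 0.08 and the salt transporter solute carrier family 12 member 1 by 1.45 ± 0.17.

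Genes of innate immunity fell at 3.4 mg/L TNT. Of 10 measured genes of the interferon response and antigen presentation, 5 fell and none rose, also adjusted over the list alone, with a median of -1.04 (camera adjusted p = 1.35e-08; adjusted p = 0.00281 with an estimated correlation). Interferon regulatory factor 1 changed by -1.35 ± 0.14 (adjusted p = 1.84e-05), the RNA sensor DDX58 by -1.23 ± 0.14 and the immunoproteasome subunit PSMB8 by -1.87 ± 0.27. Of 12 genes of inflammation and the acute phase, 4 fell, 5 adjusted over the list alone (camera adjusted p = 0.00141; adjusted p = 0.0184 with an estimated correlation), including the NF-kappa-B inhibitor alpha, NFKBIA (-0.62 ± 0.07), which restrains inflammation rather than driving it, and inducible nitric oxide synthase (-2.35 ± 0.30). Complement and coagulation genes fell in 5 of 19 and rose in 1, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0026; adjusted p = 0.0337 with an estimated correlation). Complement C3, the central complement protein, changed by -0.70 ± 0.08 and complement factor B by -2.97 ± 0.40 (adjusted p = 0.000178). The member that rose was fibrinogen gamma chain-like (2.37 ± 0.44), at 2.69 CPM. Of 11 liver secreted proteins, 5 fell and 1 rose, 6 and 3 adjusted over the list alone (camera adjusted p = 0.00128; adjusted p = 0.0473 with an estimated correlation). That list fell by its median (-0.58) and by the test, but its mean was 0.34. Transthyretin, the thyroid hormone carrier, changed by -2.25 ± 0.20 and fetuin-B by -1.38 ± 0.19.

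Genes expressed in the gut lining and in connective tissue fell as well. Of 17 intestinal epithelium genes, 11 fell and none rose, 14 adjusted over the list alone, with a median of -0.78 (camera adjusted p = 4.39e-10; adjusted p = 0.0552 with an estimated correlation). Intestinal maltase-glucoamylase, a starch-digesting enzyme of the brush border, changed by -1.15 ± 0.16, the sodium/glucose cotransporter 1-like by -0.92 ± 0.13, intestinal fatty acid-binding protein FABP2 by -1.68 ± 0.28 and angiotensin-converting enzyme 2 by -0.90 ± 0.15. Of 29 collagen and matrix genes, 11 fell and none rose, 15 adjusted over the list alone (camera adjusted p = 5.78e-07; adjusted p = 0.0692 with an estimated correlation), including periostin (-0.91 ± 0.11), collagen type IX alpha 1 (-1.12 ± 0.15) and the collagen crosslinker protein-lysine 6-oxidase (-1.01 ± 0.15). The lists of larval skin (6 of 21 genes), muscle contraction (6 of 31), ribosomal proteins (5 of 23), nuclear-encoded oxidative phosphorylation (4 of 13) and the urea cycle (4 of 15) fell by camera at adjusted p = 0.00671, 0.0135, 0.00233, 0.00996 and 0.0152. The counts adjusted over the list alone were 7, 6, 7, 5 and 4. None of the 5 kept its call with an estimated correlation (adjusted p = 0.116, 0.269, 0.268, 0.205 and 0.116 with an estimated correlation). Mucin-2-like (-2.80 ± 0.43), myosin-4-like (-1.82 ± 0.21), cardiac troponin C (-1.36 ± 0.18) and argininosuccinate synthase (-1.36 ± 0.14) were among their members.

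The TNT response widened with dose. The number of changed transcripts was 349 at 1.5 mg/L (222 up, 127 down), 682 at 2.3 mg/L (386 up, 296 down) and 1516 at 3.4 mg/L, and 1456 had a slope over the dose steps (773 up, 683 down). Transcripts of hsp70 were higher by 2.25 ± 0.44, 3.59 ± 0.46 and 4.60 ± 0.47 at the 3 doses, and the slope was 1.47 ± 0.16 per step (adjusted p = 1.32e-05). The cystine/glutamate transporter rose by 1.98 ± 0.23, 2.85 ± 0.23 and 3.66 ± 0.24, with a slope of 1.15 ± 0.10 (adjusted p = 3.02e-06). Glutathione S-transferase alpha 1 rose by 0.76 ± 0.13, 1.21 ± 0.13 and 1.54 ± 0.13. The row named cytochrome P450 had no such slope, at 7.02 ± 0.62, 6.88 ± 0.62 and 6.18 ± 0.60 (slope 0.80 ± 0.63, adjusted p = 0.567). The NRF2 list had 7 members up at 1.5 mg/L (camera adjusted p = 3.28e-15) and 9 at 2.3 mg/L (camera adjusted p = 1.72e-19). The interferon list had 1 and 5 members down (camera adjusted p = 6.12e-07 and 3.74e-08), and the intestinal list had 1 member down at 2.3 mg/L (camera adjusted p = 0.014; adjusted p = 0.477 with an estimated correlation). Of the 42 lists tested, 21 passed at 3.4 mg/L, 9 upward and 12 downward, and 10 did so with an estimated correlation.

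**Figure D1:**
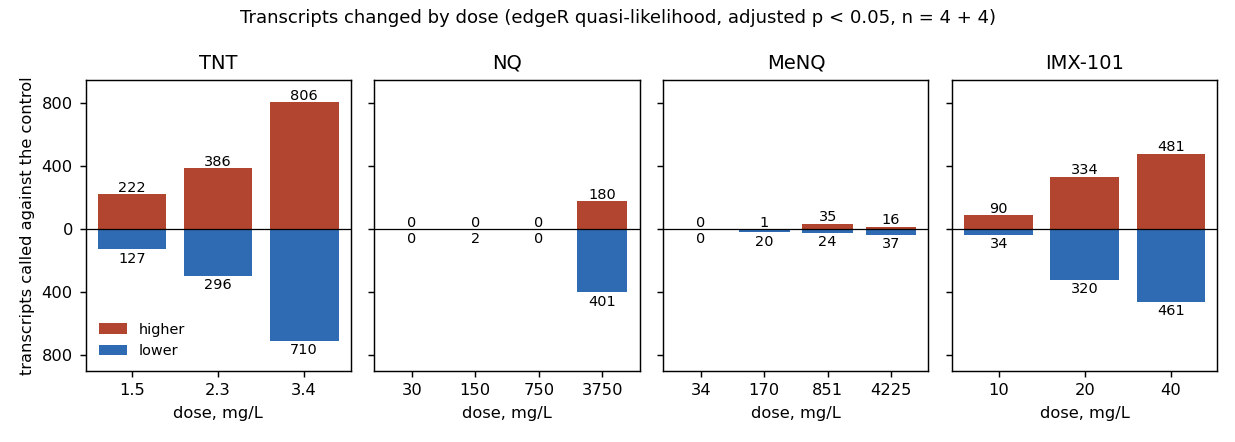
Number of transcripts that changed against the control of the same exposure (edgeR, adjusted p under 0.05) at each dose, with those higher drawn above 0 and those lower drawn below. The TNT counts grow from 349 at the lowest dose to 1516 at the highest, and NQ has 581 at 3750 mg/L against 0, 2 and 0 at its 3 lower doses.

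The second question was whether nitroguanidine, a component of the newer mixture, changed the tadpoles. NQ changed few transcripts until the highest dose. At 3750 mg/L, mast cell protease 1A-like fell by 2.08 ± 0.21, from 17.2 ± 5.47 to 4.06 ± 0.68 (SD) CPM (adjusted p = 0.000106). The protein LEG1 homolog, a secreted protein, rose by 1.32 ± 0.20, from 26.3 to 65.9 CPM (adjusted p = 0.00171). The gelatinase MMP9 fell by 1.85 ± 0.31, from 42.6 to 11.8 CPM (adjusted p = 0.00344), and interferon regulatory factor 8, a factor of myeloid cells, fell by 0.78 ± 0.15. Mucin-2-like, a mucus protein, changed by -1.98 ± 0.38 (adjusted p = 0.00701) and the secretory chaperone anterior gradient protein 2-B by -1.15 ± 0.20 (adjusted p = 0.00384), while the larval skin list that holds both did not pass (camera adjusted p = 0.563). Argininosuccinate synthase, an enzyme of the urea cycle, rose by 0.60 ± 0.13 (adjusted p = 0.0162), cytochrome P450 2G1-like by 0.86 ± 0.18 and matrix metalloproteinase-15-like by 0.57 ± 0.12. Mitochondrial thioredoxin changed by -0.50 ± 0.09 and the water channel aquaporin-4-like by -0.75 ± 0.13. The urea transporter 2-like rose by 1.27 ± 0.28 (adjusted p = 0.0166), a call that was lost without control B or control C (adjusted p up to 0.0553).

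At 3750 mg/L NQ, 581 of 12969 transcripts changed, 180 upward and 401 downward, of which 136 changed at least 2-fold. The count depended on single libraries: without control B or C it was 327 and 337, and without exposed A or C it was 255 and 324. At 150 mg/L, 2 transcripts fell, calpain-2 catalytic subunit-like (-0.86 ± 0.11, adjusted p = 0.00719) and a hypothetical protein (-0.74 ± 0.12, adjusted p = 0.0457). That count was 1 without control A, control B or exposed A, 4 without control C, 11 without control D, and 0 without exposed B, C or D. No transcript passed edgeR's test at 30 or 750 mg/L, where 1057 and 875 had an unadjusted p under 0.05 and DESeq2 called 40 up and 61 down at 30 mg/L and 91 in all at 750 mg/L. Those counts of 0 became 2 without control B, 1 without exposed B or exposed D at 30 mg/L, and 1 without control D at 750 mg/L. Over the dose steps 160 transcripts had a slope, 51 upward and 109 downward. That count fell to 63 without control C, to 106 and 83 without libraries B and D of 30 mg/L, and to 37, 51, 30 and 53 without libraries A, B, C and D of 3750 mg/L.

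A set of transcripts was present in the NQ controls and nearly absent at 3750 mg/L. Of the 581 changed transcripts, 27 had at most 3 counts over the 4 exposed libraries. A tubulin beta 2C transcript had 950 control counts and none at 3750 mg/L, at least 291-fold lower against a floor of 3 counts over the group. Transcripts of cathepsin L2, a lysosomal protease, fell from 282 counts to 1, a ratio of 259.5 (95% counting interval 46.2 to 10290). Dispanin subfamily A member 2b-like fell from 461 to 2 counts (ratio 212, interval 58.4 to 1757), an Actin, cytoplasmic 2 transcript from 478 to 3 (ratio 147, interval 49.9 to 714) and an Rpl15 transcript from 249 to 3 (ratio 76.4, interval 25.8 to 373). The control level of the 27 varied widely between libraries, at 168 ± 99.8 (SD) summed CPM, against 0.47 ± 0.34 at 3750 mg/L, where they were chosen for being low. Part of the 27 were nearly absent from other groups too, controls included: 5 had at most 3 counts at 4225 mg/L MeNQ and 6 in the MeNQ control, 7 at 3.4 mg/L TNT and 13 in the TNT control, and 18 at 40 mg/L IMX-101 and 6 in the IMX-101 control. Paralogs of actin, tubulin and ribosomal proteins share sequence, so these single values are uncertain.

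Among the gene lists at 3750 mg/L NQ, genes of growth fell and genes of plasma proteins rose by camera, and none of these calls held with an estimated correlation. Ribosomal proteins fell in 5 of 19 genes, 12 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 2.17e-07). DNA replication genes fell in 3 of 21, 9 adjusted over the list alone, with a median of -0.57 (camera adjusted p = 1.41e-06). Proteasome subunits fell in 5 of 11, 9 adjusted over the list alone, including PSMA6 (-0.63 ± 0.11) and PSMB5-like (-0.67 ± 0.12) (camera adjusted p = 1.41e-06). Complement and coagulation genes rose in 3 of 21, 5 adjusted over the list alone (median 0.70, camera adjusted p = 2.49e-06), liver secreted proteins in 2 of 10, also adjusted over the list alone (camera adjusted p = 0.000412), and cytochrome P450 families 2 and 3 in 1 of 8, 3 adjusted over the list alone (camera adjusted p = 0.0391). All 6 lists stood at adjusted p = 0.375 with an estimated correlation. The last list lost its call without control B, control C, exposed A or exposed B, with adjusted p up to 0.162. Camera also called the DNA replication list down at 30 mg/L (adjusted p = 2.09e-05) and 750 mg/L (adjusted p = 0.00036), although none of its members passed alone there, and both calls were lost with an estimated correlation (adjusted p = 0.434 and 0.589 with an estimated correlation). NRF2 targets did not pass at 3750 mg/L NQ, with 0 of 20 members changed by edgeR and a median of 0.29 (camera adjusted p = 0.249).

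MeNQ, the methylated analog, was given at the same molar concentrations. At 4225 mg/L, transcripts of v-fos, an immediate-early transcription factor, fell by 4.91 ± 0.63 (adjusted p = 0.0011), from 921 ± 425 (SD) to 30.6 ± 19.7 CPM. Nuclear receptor subfamily 4 group A member 2, also an immediate-early gene, fell by 1.60 ± 0.18, from 58.3 to 19.3 CPM (adjusted p = 0.000403). RNA-binding protein 25, a splicing regulator, rose by 1.05 ± 0.14, from 54.0 to 112 CPM (adjusted p = 0.002). The interleukin-17 receptor D rose by 1.02 ± 0.16 (adjusted p = 0.00588) and a transcript named bifunctional protein GlmU-like by 0.62 ± 0.10 (adjusted p = 0.00605). These 5 genes kept their calls whichever library was left out. A further 3 immediate-early or stress genes fell, ATF-3-like (-2.37 ± 0.43), egr2 (-1.97 ± 0.35) and CYR61-like (-2.34 ± 0.49), but lost their calls without control A, B or C or without exposed B, C or D, and the last 2 also without exposed A, with adjusted p up to 0.0757, 0.0735 and 0.148. Argininosuccinate synthase rose by 0.92 ± 0.18 (adjusted p = 0.0301), a call lost without control A, B or D or exposed A, C or D (adjusted p up to 0.131). Neuromodulin-like, a growth-cone protein, rose by 0.53 ± 0.09 (adjusted p = 0.0173), a call lost without control A, B or C or exposed A or B (adjusted p up to 0.0747).

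The immediate-early genes were high in the MeNQ controls themselves. Over 10 measured immediate-early markers, the mean log2 level was 5.52 ± 0.28 (SD, n = 4) in the MeNQ control, against 3.53 ± 0.42 in the NQ control, 3.17 ± 0.36 in the TNT control and 4.10 ± 0.20 in the IMX-101 control (exact permutation tests, two-sided, p = 0.0286 for each). The 4 MeNQ dose groups stood at 4.61, 3.92, 4.76 and 3.92 in order of dose, each below the MeNQ control (same exact test, p = 0.0286 for each). Transcripts of v-fos averaged 917 CPM in the MeNQ control, 390 at 34 mg/L, 72.9 at 170 mg/L, 479 at 851 mg/L and 30.4 at 4225 mg/L, against 19.7 in the NQ control, 26.9 in the TNT control and 161 ± 112 (SD) in the IMX-101 control.

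**Figure D2:**
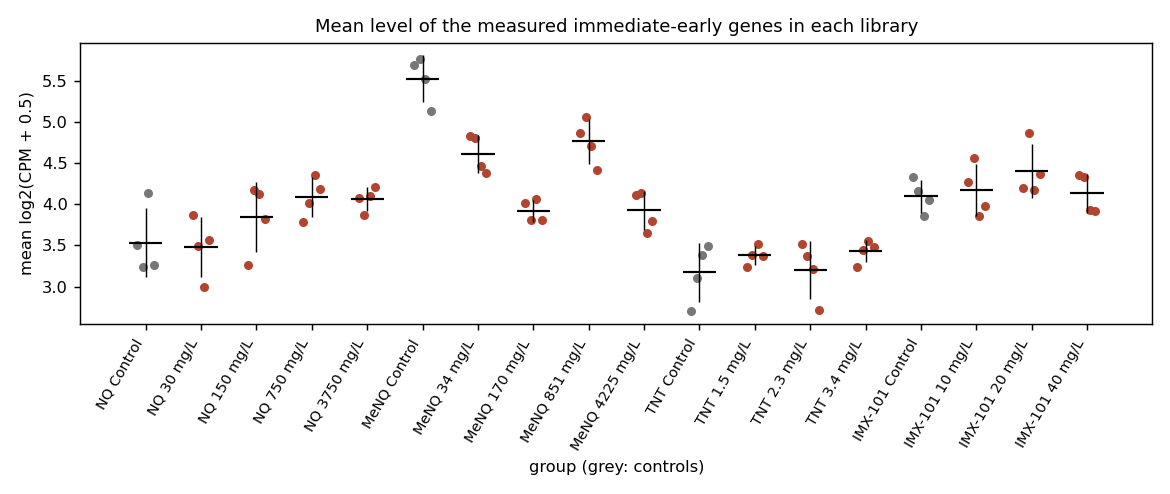
Mean log2 level of 10 immediate-early markers in each library (points) with the group mean and SD, for the control and every dose of the 4 exposures. The MeNQ control mean, 5.52, lies above the other 3 control means, and 170 and 4225 mg/L MeNQ share a mean of 3.92.

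In number, 53 of 13496 transcripts changed at 4225 mg/L MeNQ (16 up, 37 down), 59 at 851 mg/L (35 up, 24 down), 21 at 170 mg/L (1 up, 20 down) and 0 at 34 mg/L, where edgeR gave 652 an unadjusted p under 0.05 and DESeq2 called 71. These counts moved with single libraries. At 4225 mg/L, without control A, B, C or D, 21, 17, 24 and 83 transcripts passed, and without exposed A, B, C or D, 27, 24, 24 and 30. At 851 mg/L, 33, 26 and 18 passed without control A, B or D, and 37, 29 and 32 without exposed A, B or C. At 170 mg/L, 5, 9 and 10 passed without control A, B or C, and 9, 5, 5 and 4 without exposed A, B, C or D. At 34 mg/L, 1, 2 and 4 passed without control B, C or D, and 1 without exposed D. A slope over the dose steps was found for 12 transcripts, and for 2, 25 and 29 without control A, C or D, 19 without 34 mg/L B, and 23 and 24 without 851 mg/L A or B.

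Camera called 5 of 42 lists at 4225 mg/L MeNQ, and none held with an estimated correlation. Inflammation and acute phase genes fell in 1 of 11, 3 adjusted over the list alone (camera adjusted p = 0.0262; adjusted p = 0.145 with an estimated correlation), and the member that fell was v-fos, a transcription factor. Lens and photoreceptor genes fell in 1 of 16, also adjusted over the list alone (camera adjusted p = 0.0262). No member of the complement (21 genes), fatty acid oxidation (18) or muscle contraction (31) lists passed alone by edgeR, although camera called the first 2 up and the last down (adjusted p = 0.0274 for each), and 0, 4 and 0 passed adjusted over the list alone. The fatty acid oxidation list had a median of 0.17 and a mean of -0.12. These 4 lists stood at adjusted p = 0.574 with an estimated correlation. The number of lists called was 3, 9 and 8 without control A, B or C, and 2 without exposed C. The lens list lost its call without control A or exposed C or D (adjusted p up to 0.206), the complement list without control A or D or exposed A or C (up to 0.333), the fatty acid oxidation list without control A or D or exposed C or D (up to 0.452), and the muscle list without control A or exposed A (up to 0.224).

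Whether the response to MeNQ differed from that to NQ was tested as the MeNQ change minus the NQ change at each matched dose, in 1 model of 40 libraries. At 36 mmol/L, v-fos was lower by MeNQ than by NQ, with a difference of -6.03 (95% interval -7.45 to -4.61, adjusted p = 4.53e-06). MeNQ changed it by -4.92 ± 0.53 and NQ by 1.11 ± 0.47 in that model, and the MeNQ value was measured from the high MeNQ control described above. Nuclear receptor subfamily 4 group A member 2 differed by -1.69 (-2.24 to -1.14, adjusted p = 0.000993) and ATF-3-like by -2.91 (-4.16 to -1.65, adjusted p = 0.018), both also immediate-early or stress genes. A transcript of the kruppel-like factor family of transcription factors differed by -2.71 (-3.27 to -2.15, adjusted p = 3.70e-07), and it averaged 432 CPM in the MeNQ control against 76.5 in the NQ control. Mast cell protease 1A-like differed by 1.73 (1.12 to 2.34, adjusted p = 0.00265), at -0.34 ± 0.21 under MeNQ and -2.07 ± 0.22 under NQ. The protein LEG1 homolog differed by -1.65 (-2.25 to -1.05, adjusted p = 0.00314) and the skin gene cornifelin homolog B-like by 1.40 (0.81 to 1.98, adjusted p = 0.0151). Transmembrane 4 L6 family member 20 differed by 1.66 (0.85 to 2.47) and the autophagy gene ATG3 by 1.24 (0.64 to 1.85), but both calls were lost when some single libraries were left out. The first was lost without NQ control B, C or D, NQ 3750 mg/L A, C or D, MeNQ control A, B or C, or MeNQ 4225 mg/L B, C or D (adjusted p up to 0.117), and the second without NQ control A, B, C or D, NQ 3750 mg/L A or C, MeNQ control A, B or C, or MeNQ 4225 mg/L B or C (up to 0.101). Genes that both compounds raised did not pass, which does not show that the compounds acted alike: argininosuccinate synthase differed by 0.30 (-0.16 to 0.76, adjusted p = 0.65), the interleukin-17 receptor D by 0.09 (-0.40 to 0.58, adjusted p = 0.966) and epoxide hydrolase 1-like by -0.20 (-0.69 to 0.28, adjusted p = 0.837). Mucin-2-like, which fell under NQ and did not pass under MeNQ, also missed (1.85, 0.77 to 2.94, adjusted p = 0.102).

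The number of transcripts whose response differed was 3, 18, 16 and 88 of 14068 at 0.3, 1.4, 7.2 and 36 mmol/L. At 0.3 mmol/L the 3 were ankyrin-3 (-0.99, -1.35 to -0.63), nuclear receptor subfamily 4 group A member 2 (-1.54, -2.09 to -0.996) and a hypothetical protein (-1.80, -2.50 to -1.11). All 3 lost their calls without NQ control A, B or D, NQ 30 mg/L C, MeNQ control A or B, or MeNQ 34 mg/L A, B or D, the first and last also without NQ 30 mg/L B, and the last also without NQ control C or NQ 30 mg/L D. The adjusted p then reached 0.124, 0.124 and 0.176. At 1.4 mmol/L v-fos (v-fos FBJ murine osteosarcoma viral oncogene homolog) differed by -4.36 (-5.73 to -2.98, adjusted p = 0.000797), whereas at 7.2 mmol/L its difference of -1.90 did not pass (adjusted p = 0.355). The counts moved with single libraries. At 36 mmol/L the count was 39 without NQ control C, 58 and 54 without NQ 3750 mg/L A or C, 40, 49 and 245 without MeNQ control A, C or D, and 41 and 58 without MeNQ 4225 mg/L B or D. At 7.2 mmol/L it was 2 and 1 without NQ control A or C, 7, 1 and 1 without NQ 750 mg/L A, B or C, 1 and 6 without MeNQ control A or C, and 3, 1 and 5 without MeNQ 851 mg/L A, C or D. At 1.4 mmol/L it was 36 without NQ control D, 37 and 11 without NQ 150 mg/L A or D, and 10 without MeNQ 170 mg/L A. At 0.3 mmol/L it was 0 without NQ control A, B or D, 1, 0 and 5 without NQ 30 mg/L B, C or D, 0, 0 and 9 without MeNQ control A, B or D, and 0, 0, 5 and 0 without MeNQ 34 mg/L A, B, C or D. At 36 mmol/L the median 95% interval of a difference reached 1.41 log2 to either side, and 25.7% of transcripts had an interval wholly within 1 log2 of 0. Across genes, the NQ and MeNQ changes had a Spearman correlation of 0.031 at 36 mmol/L, and genes are not independent replicates.

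Differences between the compounds in gene lists depended on the assumed correlation. At 36 mmol/L the MeNQ minus NQ difference was positive for DNA replication (camera adjusted p = 0.000372), ribosomal proteins (8.82e-07) and the proteasome (0.00594) and negative for complement and coagulation (0.0171). All 4 stood at adjusted p = 0.464 with an estimated correlation. Of the proteasome subunits that fell under NQ, PSMB5-like differed by 0.66 (0.24 to 1.08) and did not pass (proteasome subunit beta type-5-like, adjusted p = 0.14).

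The fourth exposure, IMX-101, raised some detoxification genes from its lowest dose. Its control and 10 mg/L libraries were sequenced in one set of runs, while all 8 libraries of 20 and 40 mg/L came from another set with 1 run each, so changes at 20 and 40 mg/L cannot be separated from the run set. Changes within a set, from the model of all 16 libraries, are given beside the lists and part of the genes. At 40 mg/L the transcript named only cytochrome P450 rose by 4.16 ± 0.46, from 19.6 ± 6.49 to 351 ± 171 (SD) CPM (adjusted p = 7.09e-05), and within the first set, at 10 mg/L, by 3.52 ± 0.45 (adjusted p = 0.00174). The efflux pump multidrug resistance protein 1-like rose by 2.64 ± 0.21 (adjusted p = 6.01e-06), by 1.41 ± 0.20 at 10 mg/L, and by a further 1.16 ± 0.20 between 20 and 40 mg/L, within the second set (adjusted p = 0.0231). Apoptosis-inducing factor 2-like rose by 2.09 ± 0.18, 1.12 ± 0.17 and 0.90 ± 0.17 in the same 3 comparisons (adjusted p = 1.25e-05, 0.00758 and 0.0485), and cytochrome P450 4B1-like by 1.74 ± 0.15, 0.65 ± 0.15 and 0.91 ± 0.15. The cystine/glutamate transporter rose by 2.44 ± 0.20 at 40 mg/L and 1.62 ± 0.19 at 10 mg/L (adjusted p = 8.12e-06 and 0.00144), and cytochrome P450 2H2 by 2.45 ± 0.26 and 1.22 ± 0.25. Transcripts of hsp70 rose by 3.77 ± 0.61 at 40 mg/L (adjusted p = 0.00153), while their 2.44 ± 0.58 at 10 mg/L missed (adjusted p = 0.0696).

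The largest falls at 40 mg/L IMX-101 ended at a count of 0. Golgin subfamily B member 1, a Golgi protein, had 604 control counts and none at 40 mg/L, at least 81.0-fold lower against a floor of 3 counts over the group, and aminoadipate aminotransferase, an enzyme of lysine breakdown, had 918 and none, at least 123-fold lower. Both were also lower at 40 than at 20 mg/L (adjusted p = 0.000121 and 0.0166) and did not differ from control at 10 mg/L (adjusted p = 1 and 0.997). DENN domain-containing protein 3 went from 1486 counts to none, at least 199-fold lower, but it passed within neither run set (adjusted p = 1 at 10 mg/L and 0.333 between 20 and 40 mg/L), so that its fall cannot be separated from the run set. Fatty acid synthase, which makes fatty acids, fell by 4.83 ± 0.85 at 40 mg/L, from 905 to 13 counts (adjusted p = 0.0028), and by 3.78 ± 0.79 at 10 mg/L (adjusted p = 0.035). Haemoglobin subunit alpha-3 fell by 1.68 ± 0.25 at 40 mg/L and by 1.25 ± 0.25 at 10 mg/L (adjusted p = 0.000739 and 0.0243).

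By list, NRF2 targets and conjugation enzymes rose under IMX-101. Of 18 NRF2 targets, 5 rose and none fell at 40 mg/L, or 8 and 1 adjusted over the list alone (camera adjusted p = 1.40e-06; adjusted p = 0.00678 with an estimated correlation). Its median was 0.22 but its mean was -0.19. The 5 included Fth1 (0.88 ± 0.08, adjusted p = 1.41e-05; 0.51 ± 0.08 at 10 mg/L), carbonyl reductase 1-like (1.05 ± 0.15; 0.99 ± 0.15 at 10 mg/L) and malic enzyme (0.53 ± 0.06). Of 16 conjugation enzymes, 5 rose, 7 adjusted over the list alone, with a median of 0.43 (camera adjusted p = 3.70e-06; adjusted p = 0.0259 with an estimated correlation), among them glutathione S-transferase alpha 1 (0.74 ± 0.07; 0.49 ± 0.07 at 10 mg/L) and UDP-glucuronosyltransferase 1-1-like (0.78 ± 0.08). Within the first run set, both lists also passed at 10 mg/L by camera (adjusted p = 2.12e-05 and 6.89e-05), where with an estimated correlation the first passed (adjusted p = 0.0219) and the second missed (0.05003). Neither passed between 20 and 40 mg/L (adjusted p = 0.112 and 0.335).

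Genes of cell division fell under IMX-101. DNA replication genes fell in 12 of 21 at 40 mg/L, 13 adjusted over the list alone, with a median of -0.66 (camera adjusted p = 2.08e-13; adjusted p = 0.0175 with an estimated correlation). They included the primase PRIM1 (-0.60 ± 0.07, adjusted p = 8.81e-05), the clamp loader subunit RFC5 (-0.72 ± 0.09) and the helicase subunit MCM7 (-0.89 ± 0.13). Cell cycle genes fell in 5 of 17, 8 adjusted over the list alone, with a median of -0.94 (camera adjusted p = 1.62e-06; adjusted p = 0.0259 with an estimated correlation), including the spindle checkpoint and kinetochore genes BUB1B (-0.85 ± 0.11), XMAD2 (-0.79 ± 0.12) and NUF2 (-0.66 ± 0.09). Within run sets, the DNA replication list passed at 10 mg/L (camera adjusted p = 3.03e-07; missed at adjusted p = 0.05003 with an estimated correlation) but not between 20 and 40 mg/L (0.108), and the cell cycle list passed between 20 and 40 mg/L (1.12e-05) but not at 10 mg/L (0.292). PCNA fell by 1.03 ± 0.18 and cyclin G1, a p53 target, rose by 1.14 ± 0.23 at 40 mg/L. Neither passed at 10 mg/L (adjusted p = 0.299 and 0.147) or between 20 and 40 mg/L (0.904 and 0.999).

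Lens and photoreceptor genes rose at 40 mg/L in 6 of 16, or 8 up and 1 down adjusted over the list alone (camera adjusted p = 2.04e-06; adjusted p = 0.0259 with an estimated correlation), among them the crystallins gamma-N-like (0.69 ± 0.09) and beta A1 (0.69 ± 0.12) and the long-wave opsin OPN1LW (0.61 ± 0.10). This list passed within both run sets, at 10 mg/L (camera adjusted p = 0.000178; adjusted p = 0.0708 with an estimated correlation) and between 20 and 40 mg/L (0.00154). Complement and coagulation genes rose in 5 of 21, or 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.000151; adjusted p = 0.0259 with an estimated correlation), including heparin cofactor 2 (0.57 ± 0.09) and fibrinogen beta chain-like (0.59 ± 0.09). Of 10 liver secreted proteins 4 rose, 5 adjusted over the list alone, including serotransferrin-B (0.66 ± 0.09) (camera adjusted p = 0.000151; adjusted p = 0.0569 with an estimated correlation). In the list of haem degradation and iron handling 2 of 6 rose, also adjusted over the list alone. They were Fth1 and serotransferrin-B, which store and carry iron (camera adjusted p = 0.0029; adjusted p = 0.0259 with an estimated correlation), and the list's median was 0.02 and its mean -0.38. Collagen and matrix genes fell in 7 of 30, 12 adjusted over the list alone (camera adjusted p = 5.02e-05; adjusted p = 0.0795 with an estimated correlation), with collagen alpha-1(III) at -0.78 ± 0.07 and collagen alpha-1(XII) at -0.95 ± 0.13. At 10 mg/L, within the first set, the complement (camera adjusted p = 2.02e-05), liver (3.83e-06) and collagen (0.0275) lists passed in the same directions, and the first 2 kept their calls with an estimated correlation (adjusted p = 0.0296 and 0.037, against 0.415 with an estimated correlation for collagen), while none of the 3 passed between 20 and 40 mg/L (0.681, 0.195 and 0.0546). The haem degradation list passed only between 20 and 40 mg/L (0.0273; 0.533 at 10 mg/L).

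Camera called 5 more lists upward at 40 mg/L IMX-101, each lost with an estimated correlation and without some single libraries. Muscle contraction had 7 of 30 genes up and 4 down, 10 and 5 adjusted over the list alone, with troponin T (0.79 ± 0.11) up and myosin-4-like (-1.28 ± 0.17) down. Its camera adjusted p was 0.0114 (adjusted p = 0.429 with an estimated correlation), and up to 0.0706 without control D or exposed A. Ribosomal proteins had 4 of 17 up and 1 down, 7 and 1 adjusted over the list alone (0.0172; adjusted p = 0.445 with an estimated correlation; up to 0.161 without control A or exposed A or D). The mean of each of these 2 lists was below 0 (-0.010 and -0.42) and the median above (0.39 and 0.24). Antioxidant enzymes had 2 of 12 up (0.026; adjusted p = 0.125 with an estimated correlation; 0.0557 without exposed A), among them selenoprotein Pb-like (0.85 ± 0.10). The circadian list had 1 of 14 up, the repressor NFIL3 (1.09 ± 0.11) (0.0288; adjusted p = 0.25 with an estimated correlation; up to 0.0918 without control D or exposed A or B). The unfolded protein list had 3 of 15 up, the cystine/glutamate transporter, ATF5 (0.75 ± 0.11) and ATF-3-like (1.93 ± 0.40), which act in the amino acid arm of that response. Its median was -0.13 and its mean -0.28 although the test was upward (0.0288; adjusted p = 0.138 with an estimated correlation; up to 0.109 without control B or C or exposed A). At 10 mg/L, within the first set, the ribosomal (camera adjusted p = 0.0174; 0.586 with an estimated correlation) and unfolded protein lists (0.00252; 0.05003 with an estimated correlation) passed by camera and the muscle, antioxidant and circadian lists did not (0.202, 0.0846 and 0.814), and none of the 5 passed between 20 and 40 mg/L (0.145 to 0.749).

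In number, 124 transcripts changed at 10 mg/L IMX-101 (90 up, 34 down), 654 at 20 mg/L (334 up, 320 down) and 942 of 12542 at 40 mg/L (481 up, 461 down), 211 of these at least 2-fold, and 969 had a slope over the dose steps. The counts moved with single libraries. At 10 mg/L, 79, 67 and 72 passed without control A, B or D and 54, 44 and 81 without exposed A, B or C. At 20 mg/L, 421 and 344 passed without control A or D and 317, 426 and 327 without exposed B, C or D. At 40 mg/L, 611 passed without control D and 624 without exposed A, and 645 had a slope without control D. Within the second run set, 38 transcripts differed between 40 and 20 mg/L (14 up, 24 down) in the model of all 16 libraries, and 2 (1 up, 1 down) in a fit of the 8 libraries of that set alone. Of the 942, 808 (85.8%) passed within neither run set. Agreement in sign would decide nothing, because the comparisons share libraries.

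**Figure D3:**
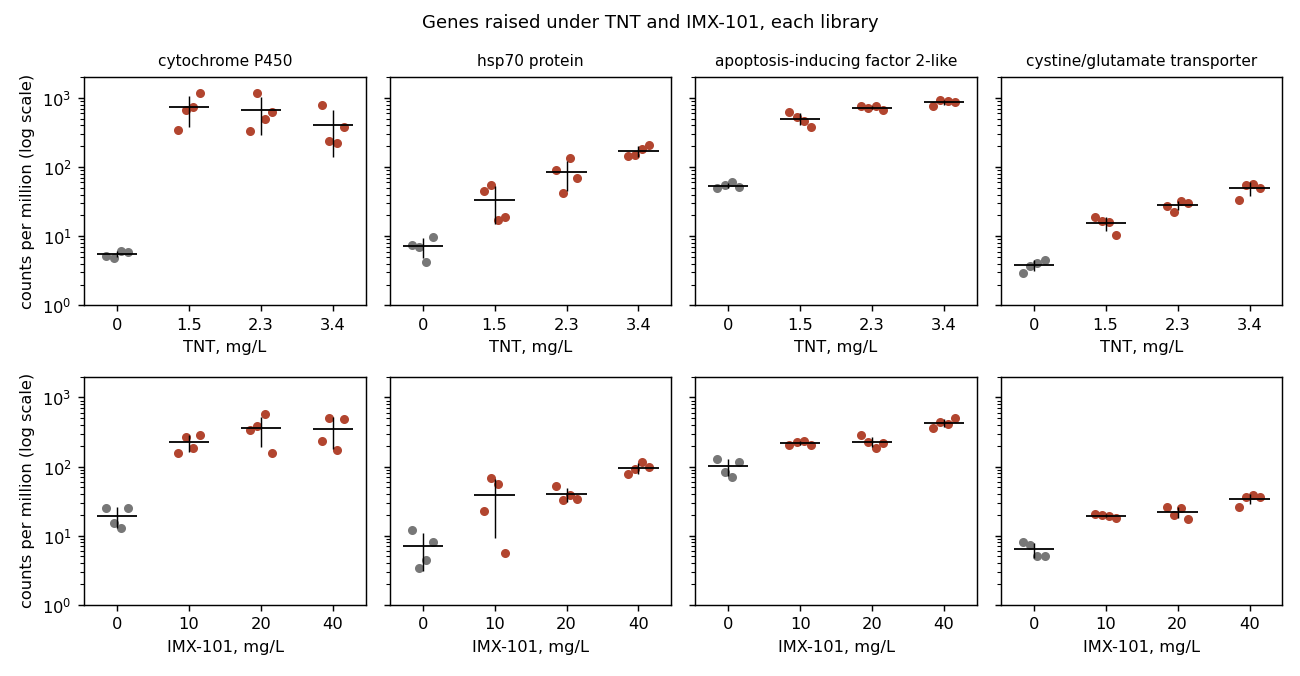
Levels in CPM (log scale) of 4 genes in each library (points) at each dose of TNT and IMX-101, with the group mean and SD. The cytochrome P450 row goes from 5.56 in the TNT control to 408 at 3.4 mg/L, and from 19.6 in the IMX-101 control to 351 at 40 mg/L.

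Some genes changed the same way under 2 exposures. Of 11842 transcripts tested under both TNT and IMX-101, 203 changed in the same direction at the highest doses (107 up, 96 down), where independent calls would give 59.2, and 124 changed in opposite directions, where independent calls would give 59.0. Those shared upward included the genes cytochrome P450, hsp70, apoptosis-inducing factor 2-like, the cystine/glutamate transporter, multidrug resistance protein 1-like (3.63 ± 0.22 under TNT) and pirin, an iron-binding nuclear protein (3.28 ± 0.22 and 1.67 ± 0.12). Cytochrome b-5, an electron carrier for P450 enzymes, rose by 1.04 ± 0.11 and 0.93 ± 0.12. Those shared downward included mucin-2-like (-2.80 and -1.07), inducible nitric oxide synthase (-2.35 and -1.35), caveolin 1 (-1.24 and -0.66) and collagen alpha-1(III) (-0.56 and -0.78). Opposite changes included haemoglobin subunit alpha-3 (1.56 and -1.68) and crystallin beta A1 (-0.63 and 0.69), although the difference between the exposures was not tested. Across all genes the TNT and IMX-101 changes had a Spearman correlation of -0.013, where genes are not independent replicates. Pirin, multidrug resistance protein 1-like, caveolin 1 and cytochrome b-5 were picked here after their values were seen.

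**Figure D4:**
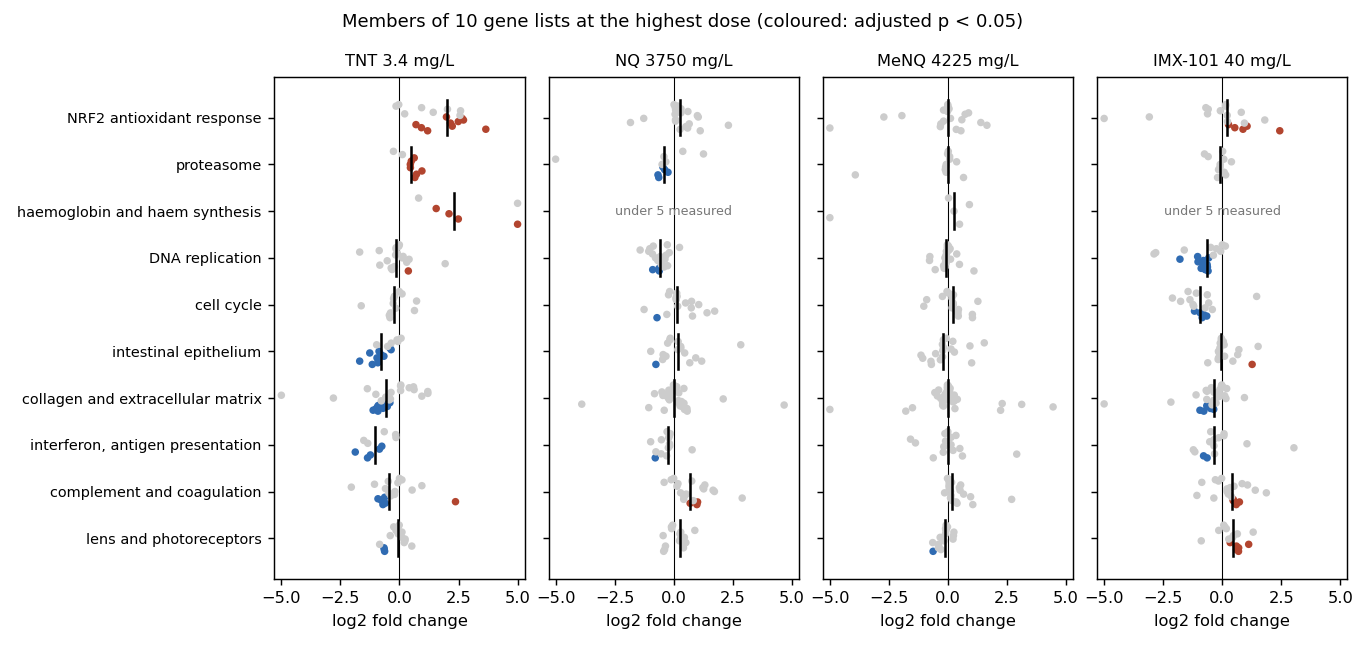
Log2 fold change of each measured member (points, drawn at 5 where beyond it) of 10 gene lists at the highest dose of each exposure, with the list median as a bar, and members that changed in colour. Of the NRF2 targets, 10 rose under TNT and 5 under IMX-101, while DNA replication genes fell in 12 of 21 under IMX-101.

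NQ is a component of IMX-101, and 102 transcripts changed in the same direction at 3750 mg/L NQ and 40 mg/L IMX-101 (38 up, 64 down), where independent calls would give 21.6, with 25 in opposite directions. The count was 67, 49, 54 and 65 without NQ control A, B, C or D, 42 and 63 without NQ 3750 mg/L A or C, and 66 without IMX-101 control D. Anterior gradient protein 2-B fell under both (-1.15 ± 0.20 under NQ, -1.01 ± 0.10 under IMX-101). The NQ dose, 3750 mg/L, far exceeded the 40 mg/L of the whole mixture, and at 30 mg/L NQ changed 0 transcripts by edgeR. Changes at 40 mg/L IMX-101 also cannot be separated from the run set. This overlap therefore does not show NQ acting within the mixture. NQ and MeNQ shared 12 transcripts (5 up, 7 down), where independent calls would give 1.38, and had none in opposite directions, where independent calls would give 1.02. The 12 became 6, 7 and 7 without NQ control C or NQ 3750 mg/L B or D, 5, 3 and 6 without MeNQ control A, B or C, and 5, 5 and 7 without MeNQ 4225 mg/L B, C or D. The 12 included argininosuccinate synthase (0.60 ± 0.13 and 0.92 ± 0.18), the interleukin-17 receptor D (0.91 and 1.02), the detoxifying epoxide hydrolase 1-like (0.81 and 0.62), the tight junction gene claudin 4 (-0.29 and -0.36) and eukaryotic translation initiation factor 3 subunit 8 (-0.54 and -0.59). These counts of independent calls assume that genes vary separately, which they do not.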

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

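The tests of the immediate-early level, of the IMX-101 run sets and of the transcripts near 0 at 3750 mg/L NQ were chosen after the result was seen, except the count of such transcripts in other groupings of the libraries, which was planned.

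Some libraries lay far from the other 3 of their group. In each group of 4 the gap of the outermost library to its nearest neighbour was compared with the range. Of 338 such groups, 24 exceeded the limit that chance exceeds in about 5%: 6 of 72 on measures of a whole library and 18 of 266 on genes named here. TNT 1.5 mg/L A held 4.29 M counts, against 13.3 to 13.99 M in the other 3. Transcripts with a count numbered 11010.0 in TNT control A (13785 to 13955 in the others), 13171 in TNT 1.5 mg/L A (14005 to 14122) and 13563 in MeNQ 4225 mg/L B (14135 to 14196). The mean correlation with the rest of the group was 0.789 for TNT control A (0.839 to 0.842 for the others) and 0.833 for TNT 1.5 mg/L A (0.866 to 0.868). TNT control A was also the shallowest library of all.

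Single genes stood apart in 1 library in the following cases, given in CPM with the range of the other 3. Under TNT, adult alpha globin was 0.185 in control B and 0 in the others, and fibroblast growth factor 19 was 0.282 at 3.4 mg/L A and 0 in the others. Glutathione S-transferase alpha 1 was 127 in control A (178 to 185), myelin proteolipid protein B 345 in control A (212.5 to 228), protein-lysine 6-oxidase 27.4 in control C (42.4 to 44.8), myosin-4-like 713 in control B (517 to 539), argininosuccinate synthase 664 in control D (510.1 to 529.9), and CYP2J2 152 at 3.4 mg/L D (172 to 175). Under NQ, mast cell protease 1A-like was 25.3 in control C (13.8 to 15.5), mucin-2-like 140.4 in control B (35.3 to 42.8) and urea transporter 2-like 38.4 in control A (19.6 to 21.4). Aquaporin-4-like was 31.3 at 3750 mg/L A (38.1 to 39.4), cathepsin L2 0.114 at 3750 mg/L A (0 in the others) and calpain-2 catalytic subunit-like 57.2 at 150 mg/L A (52.0 to 52.8). Under MeNQ, v-fos was 59.9 at 4225 mg/L A (18.3 to 25.2) and egr2 11.96 in control D (24.0 to 25.1). Under IMX-101, the cystine/glutamate transporter was 25.6 at 40 mg/L A (36.8 to 38.6) and haemoglobin subunit alpha-3 10740.0 in control B (7373 to 7866).

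The response to MeNQ differed from that to NQ, by a test of the difference, in 3, 18, 16 and 88 transcripts at 0.3, 1.4, 7.2 and 36 mmol/L. At 0.3 mmol/L these were a hypothetical protein (-1.80 log2, MeNQ minus NQ), ankyrin-3 (-0.99) and nuclear receptor subfamily 4 group A member 2 (-1.54), and each lost its call when single libraries were left out. The differences named at 36 mmol/L were mast cell protease 1A-like (1.73), transmembrane 4 L6 family member 20 (1.66), cornifelin homolog B-like (1.40), ATG3 (1.24), v-fos (-6.03), ATF-3-like (-2.91), a transcript of the kruppel-like factor family (-2.71) and nuclear receptor subfamily 4 group A member 2 (-1.69). Cathepsin L2 differed by 6.93 (3.82 to 10.04, adjusted p = 0.0222), which rests on 1 count at 3750 mg/L NQ and depends on the prior count. Its call was lost without NQ control A or C, NQ 3750 mg/L C or D, or MeNQ control A or C (adjusted p up to 0.0662). RING finger protein 10-like had a fitted difference of -15.96, which rests on no counts at 4225 mg/L MeNQ and 1 count in the NQ control, so it depends on the prior count and is no bound. Its call was lost without NQ control C or MeNQ 4225 mg/L B (adjusted p up to 0.0549).

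Gene lists differed between the compounds by camera as follows, given as adjusted p and as higher or lower under MeNQ than under NQ. At 0.3 mmol/L, cholesterol synthesis (0.00929), DNA replication (0.00929) and the proteasome (0.0437) were higher, and the interferon response (0.0437), larval skin (0.0114) and muscle contraction (0.0114) lower. At 1.4 mmol/L, complement (0.0115), leukocyte markers (0.0115), pancreatic enzymes (0.000126) and intestinal epithelium (0.00735) were higher, and lens and photoreceptors (0.036) lower. At 7.2 mmol/L, oxidative phosphorylation (0.0273), ribosomal proteins (2.35e-07), complement (0.00924) and leukocyte markers (0.00821) were higher. At 36 mmol/L, DNA replication (0.000372), ribosomal proteins (8.82e-07) and the proteasome (0.00594) were higher, and complement (0.0171) lower. None of these passed with an estimated correlation, where adjusted p ran from 0.144 to 0.624.

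Other groupings of the same libraries were counted for 29 results. In 24 of them the real grouping was the only 1 with as many calls. The share of the real grouping was then the smallest possible: 2.86% for 35 groupings, 4.55% for 22 and 1.0% for 100. These shares were not adjusted over the 29 results, so chance is not excluded by them. For TNT the real counts were 349, 682 and 1516 and the highest in another grouping 1, 2 and 3, and for slopes 1456 and 2. For NQ they were 2 at 150 mg/L (highest other 0), 581 at 3750 mg/L (highest other 1) and 160 slopes (highest other 4). At 30 and 750 mg/L the comparison decides nothing, because all 35 groupings must reach the real count of 0 by edgeR (highest other 2 and 1). There 1057 and 875 transcripts had an unadjusted p under 0.05, and DESeq2 called 40 up and 61 down, and 91. For MeNQ the counts were 21, 59 and 53 at 170, 851 and 4225 mg/L (highest other 1, 1 and 0), with 12 slopes (highest other 2). At 34 mg/L it cannot: all 35 groupings gave as many as the real 0 by edgeR (652 at unadjusted p under 0.05, 71 by DESeq2), and another gave 466, which points to a structure of these 8 libraries apart from exposure. For IMX-101 the counts were 124, 654 and 942 with 1 as the highest other each time, and 969 slopes with 2. At 20 and 40 mg/L the real grouping was also that of the run sets. The differences between compounds numbered 3, 18, 16 and 88 (highest other 2, 1, 1 and 1 of 22 regroupings). For the shared transcripts (12, 203 and 102) the highest other was 0 by edgeR in each, which decides nothing. No other grouping gave more than 3 calls at a highest dose, so next to nothing could be shared.

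For the number of gene lists called by camera, the real grouping gave the most for TNT (21, highest other 11) and IMX-101 (14, highest other 13). That is the smallest share that 35 groupings allow, and the real IMX-101 grouping was also that of the run sets. Chance is thus not excluded for either. For NQ 13 of 35 groupings gave as many as the real 6 (highest other 12), and for MeNQ 9 of 35 gave as many as the real 5 (highest other 8). Camera with the preset correlation thus called many lists in groupings that mixed exposed and control libraries.

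The fall of immediate-early genes at 4225 mg/L MeNQ may reflect a high level in the MeNQ controls. Over the markers, the MeNQ control stood a median 1.333 log2 above the mean of the other 3 controls, while the 4225 mg/L libraries stood at a median -0.004 from them. Single markers at 4225 mg/L ran from -1.188 (v-fos) to 1.019 (ATF-3-like). A graded lowering by MeNQ is argued against by 851 mg/L, which lay 0.839 above 170 mg/L (exact permutation p = 0.0286, the smallest 4 against 4 libraries allow). By the same exact test the level did not differ from control at p under 0.05 at the highest dose of NQ (0.526, p = 0.114), TNT (0.256, p = 0.229) or IMX-101 (0.033, p = 0.771). An effect of MeNQ that has no order by dose, and a difference in how the control tadpoles were handled, stay open and were not tested.

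The 27 transcripts that were nearly absent at 3750 mg/L NQ could come from another organism in the samples, or be present in some groups and absent from others whatever the exposure. Over the 16 libraries of the control and lower doses they varied together weakly, with a median pairwise Spearman correlation of 0.095 against 0.003 in 1000 sets of transcripts matched on mean count (95th percentile 0.041, none as high). Of the 27, 15 had at most 3 counts over the control of another exposure, against a median of 2 in the matched sets (95th percentile 4), so their absence also went with groups that had no exposure. A lower depth is argued against by the 191.67 counts (median) expected in the exposed libraries at the control rate, while the highest number of such transcripts in another grouping, 1, decides nothing because no other grouping gave more than 1 call of any kind. Reads shared with paralogs and a lowering of these genes in the tadpoles themselves stay open and were not tested.

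The changes at 20 and 40 mg/L IMX-101 might stem in part from the separate sequencing run set. As the whole cause it is argued against for the NRF2 list only. That list passed at 10 mg/L within the first run set (camera adjusted p = 2.12e-05, or 0.0219 with an estimated correlation). The DNA replication list missed there with an estimated correlation (3.03e-07, then 0.05003). The cell cycle list, at 40 against 20 mg/L within the second set, had only the preset correlation (1.12e-05, model of 16 libraries). Camera so set called up to 13 lists in mixed IMX-101 groupings, so neither decides. For the 808 transcripts called at 40 mg/L and in neither comparison within a run set, exposure and run set cannot be told apart, because every library of 20 and 40 mg/L came from the second set.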

How the results depend on the processing

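The alternatives given above as added later were chosen after seeing the data, and the others were planned. No value that passed as planned changed direction: over all alternatives, 0 of 12691 values for named genes and 0 of 2323 for gene lists were so reversed. Among values that did not pass as planned, 69 for named genes and 143 for lists changed direction. For named genes 11666 kept their direction and their side of the threshold, 787 no longer passed and 169 newly passed. For lists these numbers were 2044, 81 and 55. Of 584 recomputed counts, 385 stayed within 1.5 times the planned count. The median change over all genes moved by less than 0.1 log2 under each scaling. Except where the construction of an alternative shows it, the cause was not tested.

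With each library left out in turn, the counts of changed transcripts ran from 241 to 296 at 1.5 mg/L TNT, 488 to 616 at 2.3 and 1107 to 1421 at 3.4, with 1160 to 1457 slopes. For NQ they ran from 0 to 2 at 30 mg/L, 0 to 11 at 150, 0 to 1 at 750 and 255 to 476 at 3750, with 30 to 202 slopes. For MeNQ they ran from 0 to 4 at 34 mg/L, 4 to 16 at 170, 18 to 48 at 851 and 17 to 83 at 4225, with 2 to 29 slopes. For IMX-101 they ran from 44 to 98 at 10 mg/L, 317 to 721 at 20 and 611 to 821 at 40, with 645 to 990 slopes. Differences between MeNQ and NQ ran from 0 to 9, 10 to 37, 1 to 20 and 39 to 245 in order of dose. Shared transcripts ran from 149 to 199 for TNT with IMX-101, 42 to 95 for NQ with IMX-101 and 3 to 12 for NQ with MeNQ. Called lists ran from 19 to 22 for TNT, 5 to 7 for NQ, 2 to 9 for MeNQ and 10 to 15 for IMX-101. A fit with a library fewer has less power by its construction.

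A 2-fold minimum left fewer calls by its construction: 122, 231 and 448 for TNT, 0 at 150 and 136 at 3750 mg/L NQ, 10, 15 and 26 at the 3 higher MeNQ doses, and 23, 126 and 211 for IMX-101. It left 2 shared transcripts for NQ with MeNQ, 51 for TNT with IMX-101 and 20 for NQ with IMX-101. Fits of only the 8 libraries of each pair of groups, with fewer libraries to estimate the spread, called 149 and 421 at 1.5 and 2.3 mg/L TNT, 1 and 98 at 150 and 3750 mg/L NQ, 4, 0 and 8 at 170, 851 and 4225 mg/L MeNQ, and 46, 264 and 525 for IMX-101. The 0 is by edgeR.

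The DESeq2 Wald test called more. It gave 736 and 1165 at 1.5 and 2.3 mg/L TNT, 1.0e+02 (40 up, 61 down), 143, 91 and 1147 for NQ with 606 slopes, 71, 190, 445 and 351 for MeNQ with 235 slopes, and 503, 1361 and 1470 for IMX-101. It gave 124, 254, 187 and 436 differences between MeNQ and NQ, and 65, 308 and 212 shared transcripts for NQ with MeNQ, TNT with IMX-101 and NQ with IMX-101. Its balance differed too, at 379 up and 357 down at 1.5 mg/L TNT, 90 and 100 at 170 mg/L MeNQ, 159 and 192 at 4225 mg/L MeNQ, and 141 and 113 for the difference at 1.4 mmol/L, against 222 and 127, 1 and 20, 16 and 37, and 6 and 12 by edgeR. On simulated counts 28.3% to 41.4% of its calls were false. With DESeq2 size factors in edgeR the majority turned at 3.4 mg/L TNT (712 up, 788 down), in the TNT slopes (701 and 749, against 773 and 683) and in the IMX-101 slopes (511 and 460, against 465 and 504). The Wald test turned it at 2.3 mg/L TNT (574 and 591, against 386 and 296), at 3.4 mg/L TNT (1010 and 1066), in the IMX-101 slopes (746 and 694) and in the differences at 36 mmol/L (211 and 225, against 46 and 42). With the size factors 1 transcript passed at 150 mg/L NQ, and 4 of 746 values for named genes no longer passed.

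Without the filter on low counts, 37 transcripts passed at 851 mg/L MeNQ, 66 had a MeNQ slope and 7 were shared by NQ and MeNQ. Summing counts by protein name gave 26 MeNQ slopes and 1 difference at 0.3 mmol/L. With log10 dose, 316 transcripts had an NQ slope and 21 a MeNQ slope. The mean of the runs gave 1 transcript at 34 mg/L MeNQ. The deepest run of each library gave 93 NQ slopes, 2 transcripts at 34 mg/L MeNQ, 20 MeNQ slopes, and 0 differences by edgeR at 0.3 and 7.2 mmol/L. The lane as a term gave 221 at 1.5 mg/L TNT, 10 at 170 mg/L MeNQ, 22 MeNQ slopes, and 4 and 162 differences at 7.2 and 36 mmol/L. Without the 2 TNT libraries of a single run, no TNT count moved by 1.5 times.

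For lists, a correlation estimated from the data left 10 calls for TNT, 0 for NQ, 0 for MeNQ and 7 for IMX-101, and fry called 1 list for MeNQ. These 0s are by camera, which with its preset correlation called 6 and 5, with fry as the other test.

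The labels give each group the letters A to D, which were not treated as pairs. The correlation between libraries of the same letter, after removing group means, ran from -0.039 to 0.085, and 0 of 14 comparisons exceeded 0.1, while 13 of 20 NQ, 9 of 20 MeNQ, 4 of 16 TNT and 1 of 16 IMX-101 libraries were closest to one of their own letter, so an effect of the letter in NQ stays open. With the letters as a replicate block, 21 transcripts passed at 150 mg/L NQ, 105 had an NQ slope, 2 had a MeNQ slope, 41 and 368 passed at 10 and 20 mg/L IMX-101, and 43 differed at 1.4 mmol/L. The other 23 of 29 counts stayed within 1.5 times.

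Not every change could be seen with the depth, spread and number of libraries at hand, which the simulation did not separate. At 3.4 mg/L TNT the simulated recovery was 20.97% at 2-fold and 49.2% at 4-fold, with 193 transcripts changed. It need not hold for the real data, with 1516 calls.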

Other observations

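Some heat shock, unfolded protein and pancreatic transcripts also changed at 3.4 mg/L TNT. The small heat shock protein beta-8 rose by 0.74 ± 0.10 (adjusted p = 0.000136), from 82.9 to 138 CPM, and the heat shock list had 2 of 6 members up, 3 adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.116 with an estimated correlation). That list lost its call without control D or exposed C (adjusted p up to 0.0615). The kinase EIF2AK3, which slows translation when proteins misfold, rose by 1.23 ± 0.24, while ATF4, which acts after it, changed by -0.23 ± 0.04. The unfolded protein list passed upward by camera with 2 of 13 up and 1 down, 3 and 1 adjusted over the list alone (adjusted p = 0.0486; adjusted p = 0.112 with an estimated correlation), a call lost without control A, B or D or exposed B, C or D (up to 0.108). Pancreatic digestive enzymes fell in 3 of 11, also adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.221 with an estimated correlation; 0.0528 without control C). The pancreatic lipase-related protein 1 changed by -2.06 ± 0.35 and colipase, a cofactor of fat digestion, by -1.14 ± 0.20, from 1393 to 632 CPM.

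In genes of bile acid and steroid metabolism, a difference between TNT doses was not tested. The list passed at 1.5 mg/L with 2 of 11 members up (camera adjusted p = 3.95e-07; adjusted p = 0.0128 with an estimated correlation) and at 2.3 mg/L with 2 up (0.00012; adjusted p = 0.0425 with an estimated correlation), and did not at 3.4 mg/L (adjusted p = 0.957). CYP8B1, an enzyme of bile acid synthesis, rose at 3.4 mg/L by 0.87 ± 0.13. Adjusted over the list alone, 5, 4 and 1 members rose and 0, 0 and 3 fell at the 3 doses. Gene lists of the lens and of glia did not pass at 3.4 mg/L TNT, although the crystallin gamma-N-like (-0.64 ± 0.10) and myelin proteolipid protein B (-0.76 ± 0.18) fell. At 851 mg/L MeNQ the ribosomal protein list passed upward (camera adjusted p = 7.23e-13; adjusted p = 0.0511 with an estimated correlation) with all 20 members above 0, of which 0 passed alone by edgeR and 13 adjusted over the list alone. At 150 mg/L NQ the intestinal list passed downward (camera adjusted p = 5.77e-08; adjusted p = 0.2 with an estimated correlation) with all 17 members below 0, of which 0 passed alone by edgeR and 8 adjusted over the list alone.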
